A study of Mus musculus with 14 samples.

How the data were processed

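Single-cell RNA was measured with the 10x Chromium droplet chemistry, which counts the 3' ends of transcripts with a unique molecular identifier (UMI) on each molecule, in 14 libraries from pancreatic tumours of 8 KPC mice. KPC mice carry mutant Kras and mutant p53 that a Pdx1-driven Cre recombinase switches on in the pancreas, and here the same recombinase also switches on YFP, so that YFP marks cells of the tumour's epithelial lineage. In 8 libraries all live cells were taken without fractionation, 1 library per animal. In 5 libraries, from 5 of the same animals, cells negative for CD45 (leukocytes), CD31 (endothelium) and YFP were sorted. In 1 library, from the 1 animal that also carried an aSMA-RFP reporter, RFP-expressing cells were sorted. Groups and animals were taken from the labels, and the animal names pair the libraries of the 2 main groups because both come from the same tumour-bearing mouse.

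The authors deposited 1 table of raw UMI counts per gene and cell, with 19266 gene symbols and 31996 cells. Per the submitters' processing notes, Cell Ranger, Seurat and the genome build mm10 were used; versions and settings are not given in the sources used here. Every value was a whole number, 26 genes had no UMI in any cell, and every cell column matched 1 sample. The cells had at least 500 UMIs, between 202 and 5994 genes and at most 9.99% mitochondrial UMIs, so the table had been filtered before deposit. Library totals ran from 959539 to 47154502 UMIs and median UMIs per cell from 1440 to 18892. No cell was identical in 2 libraries, and 599 barcodes occurred in more than 1 library. A chi-square comparison of gene counts in fibroblast-like cells (named below) covered pairs of libraries of 1 route or of 1 animal. None of these pairs lay within sampling noise (lowest chi-square per gene 4.04), and other pairs were not compared. YFP and RFP counts were not analysed here, so the sort markers were not checked in the counts. The labels describe 12 FASTQ files for each library of animals 0286, 0892 and 591 and 3 for every other library. Those 3 animals had unfractionated libraries alone, and whether the file numbers mark a sequencing batch is not stated, so comparisons within the other 5 animals are given as well.

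Counts were scaled to 10000 UMIs per cell, log-transformed and clustered in scanpy 1.11.5 (2000 variable genes, 40 principal components, 20 neighbours, Leiden resolution 1.0), which gave 39 clusters. A cluster took the name of the marker list, of 17 lists written before the data were examined, with the most members at least 2-fold higher in it and found in at least 10% of its cells, with a minimum of 3 such members. Clusters 25, 27 and 38 stayed unnamed, with 712 cells. They made up 6.23% ± 6.41 (SD, n = 5) of cells in the sort libraries and 1.70% ± 1.17 (SD, n = 8) in the unfractionated ones. The epithelial or cancer class was not compared between groups, because cluster 11, led by Gkn3, Ppy and Tff2, had 2 endocrine markers and 1 epithelial one among its top genes. All 11 epithelial markers met the naming rule in that cluster, against at most 1 of any other list. Scrublet called 42 cells (0.13%) as doublets, too few for the caller to have worked, so no cell was left out for the main values. The 855 cells with the highest scores, at an assumed rate of 0.8% per 1000 cells, were left out as an alternative instead. Free RNA was not removed.

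Counts were summed per library over fibroblast-like cells (at least 20 cells per sum) and tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F-test, Benjamini-Hochberg threshold 0.05). Standard errors are the log2 fold change divided by the square root of F. Fibroblast-like cells with at least 1 Acta2 UMI and no Fap UMI were called Acta2-positive, and those with at least 1 Fap UMI and no Acta2 UMI Fap-positive. These were summed per animal over both main groups and tested with the animal as a block. Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, then an estimated one). Lists and marker lists numbered 17 each; Acta2, Tagln, Myl9, Tpm1 and Tpm2 are in both the myofibroblastic and the contractile list. Shares were compared with two-sided exact permutation tests over libraries, or sign-flips over animals for pairs. P-values without the block measure the spread between libraries, taken as independent although some animals supplied both groups. Those with the block, and the sign-flips, measure the spread of differences within animals. Camera sets the genes of a list against the other genes, so its p-values rest on the preset or estimated correlation.

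For shares of Acta2-positive and Fap-positive cells, each cell was thinned to 1000 UMIs and shallower cells were left out. The main value is the share expected over all possible draws, computed exactly. It replaced a single random draw after single draws had been seen, and both are printed. For the 3 libraries of the aSMA-RFP animal there is no replicate, so counts carry exact Poisson intervals and shares exact Clopper-Pearson intervals at 95%, which cover counting error only. List medians there were placed among 10000 random lists of the same size matched on expression.

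Named genes followed a rule set before the data were examined: in each test the 12 highest and 12 lowest log2 fold changes past the threshold, with a mean of at least 20 CPM (UMI counts scaled to a common total per sum) and the same direction in every animal. Unnamed, mitochondrial, ribosomal protein and class-defining genes were left out. Acta2, Fap, Il6, Pdgfra, Pdpn, Cxcl12 and Tgfb1 were added everywhere, with 2 to 4 members of each described list. Between libraries of 1 animal the rule took genes with at least 50 UMIs and intervals that do not overlap.

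Each test was checked on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes had a mean of at least 20 CPM, so recovery of lower genes was not measured. No animal effect was simulated, so libraries of 1 animal were unrelated in these counts. The comparison of routes recovered 39% and 90% of the changed genes (7359 genes tested, 3 false calls). The same comparison with the animal as a block recovered 94% and 91% (6732 genes, 12 false calls), and the comparison of Acta2-positive with Fap-positive cells 76% and 99% (8140 genes, 13 false calls). The pairing was checked in the data: deviations from the group means correlated between both libraries of an animal at 0.346 to 0.718 over 5626 genes, in each animal above the highest value with another animal. Alternatives set beforehand covered DESeq2 1.42.0, size factors, no filter, doublets, stricter cell filters, other resolutions, other cell minimums, positivity at 2 UMIs, no thinning, the block and leaving out each replicate. Further ones were added after the data were seen. Coordinates are from GENCODE M21 (GRCm38, the assembly of mm10), matched by symbol. Libraries of the RFP sort entered no test between groups.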

Results

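The 14 libraries held 31996 cells and 173730941 UMIs, from 8 unfractionated tumour mixtures, 5 triple-negative sorts and 1 RFP sort. Depth differed between libraries. The triple-negative sort of animal 314B was the shallowest, with 373 cells and 959539 UMIs, and the unfractionated mixture of animal 739 the deepest, with 2325 cells and 47154502 UMIs. Median UMIs per cell lay between 1440 and 18892 in the unfractionated libraries, between 1763 and 10552 in the triple-negative sorts, and at 2348 in the RFP sort.

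The unfractionated mixtures show what the live tumour suspension contained before any selection. Leaving out the epithelial or cancer class (next paragraph), lymphocytes and macrophages were the most abundant cells: T cell-like cells made up 23.5% ± 15.4 (SD, n = 8), B cell-like cells 19.7% ± 12.7 and macrophage- or monocyte-like cells 19.6% ± 16.2. Dendritic-like cells made up 4.93% ± 3.98, fibroblast-like cells 4.54% ± 2.89 and neutrophil-like cells 4.23% ± 5.94. NK-like cells (1.96% ± 1.65), plasma-like cells (1.80% ± 1.28), acinar-like cells (1.31% ± 1.97) and endothelial-like cells (0.98% ± 0.64) were each a small part. Mesothelial-like cells, of the serosal lining, made up 0.41% ± 0.63. Perivascular-like cells, the mural cells around vessels, made up 0.23% ± 0.12.

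The epithelial or cancer class was not averaged, nor ranked against the other classes, because of cluster 11. Its top genes held 2 endocrine markers and 1 epithelial one, although all 11 epithelial markers met the naming rule in it. Cluster 11 supplied all 152 cells of the class in the mixture of 177B and 54 of 78 in that of 0286. In animal 739, 84.0% of cells were of the class, and clusters 6 and 19 of it held 59.8% and 22.8% of the mixture. Each of these 2 clusters was named on 4 of the 11 epithelial markers, with 0 among its top genes, and cluster 6 also met 2 fibroblast markers. Their name is therefore less certain than the share implies. All shares here are of captured live cells, which depend on dissociation and capture, and no share is a share of the tumour.

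**Figure D1:**
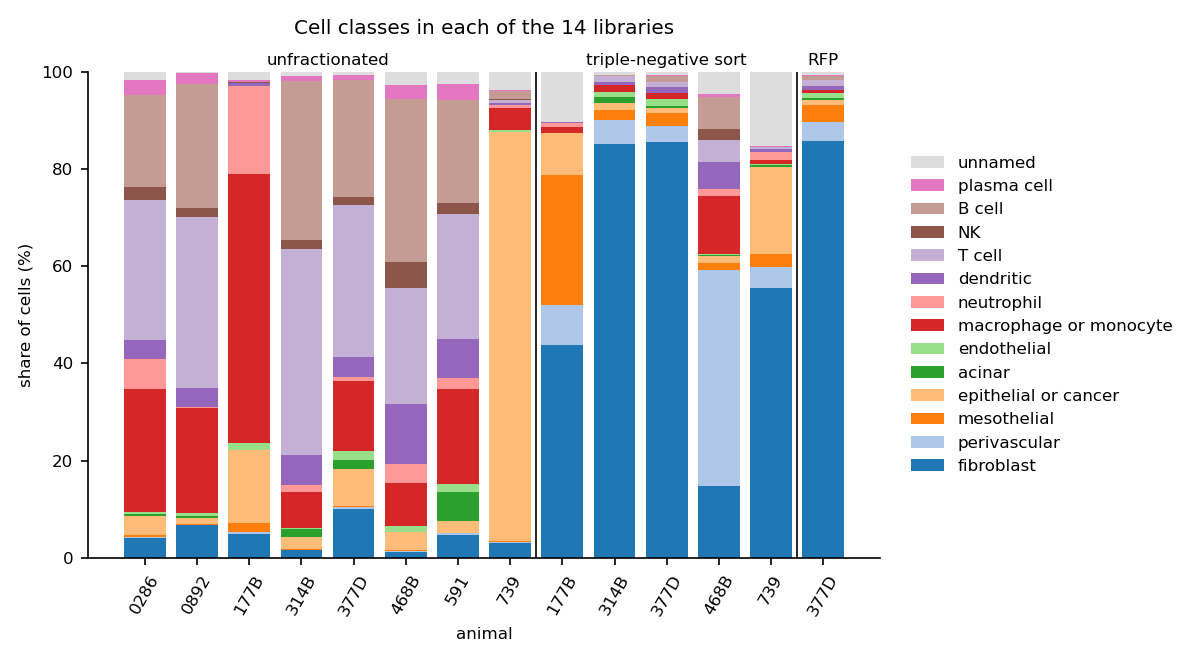
Share of cells (%) of each class in each of the 14 libraries, as stacked bars by animal and route of collection. Fibroblast-like cells (dark blue) make up 1.17% to 10.1% of the unfractionated mixtures and 14.8% to 85.5% of the triple-negative sorts.

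The triple-negative sort was designed to extract cancer-associated fibroblasts by removing leukocytes, endothelium and the YFP-marked lineage. Fibroblast-like cells rose from 4.54% ± 2.89 (SD, n = 8) of cells in the unfractionated mixtures to 57.0% ± 29.9 (SD, n = 5) after the sort. The share was higher in the sort in 5 of 5 animals with both libraries. It was lowest in animal 468B, at 14.8%, and highest in animal 377D, at 85.5%. Other non-immune classes were also present in the sort. The epithelial or cancer class was among them, as its clusters 6 and 19, each named on 4 epithelial markers, held 8.53% and 4.83% of the sort of animal 739. Perivascular-like cells averaged 13% ± 17.7 (SD, n = 5) and reached 44.5% in animal 468B, and mesothelial-like cells averaged 7.11% ± 11 and reached 26.7% in animal 177B. Macrophage- or monocyte-like cells remained at 3.25% ± 4.89.

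The difference in fibroblast share was 52.45 percentage points (two-sided exact permutation test, p = 0.0008, n = 5 and 8, the smallest p that 1287 regroupings can give). Within the 5 animals with both libraries it was 52.83 points, with p = 0.0079 (exact permutation, unpaired) and p = 0.0625 (exact sign-flip test over animals, the smallest that 5 pairs can give). The sort sets these shares, and they are not tissue composition.

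**Figure D2:**
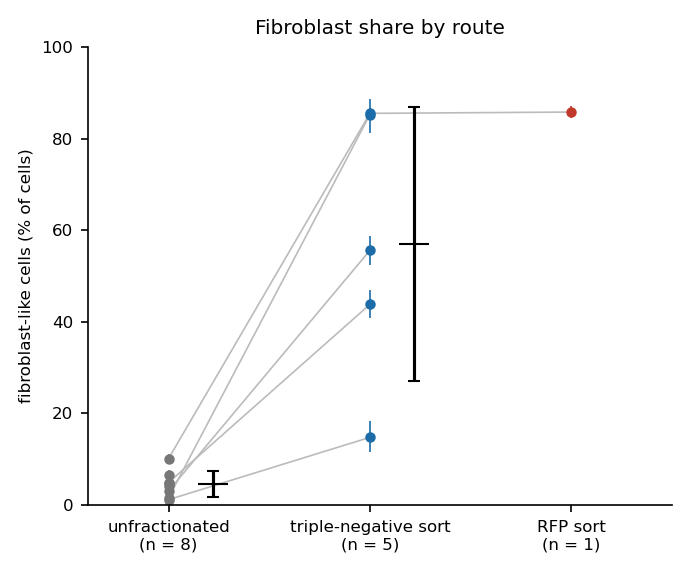
Fibroblast-like cells as a share of all cells (%) in each library, by route. Points are libraries with exact 95% binomial intervals, grey lines join libraries of 1 animal, and black bars give mean ± SD where a group has more than 1 library; all 5 sort libraries lie above their own unfractionated mixture.

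Fibroblasts obtained by both routes were compared to ask whether the sort changed which fibroblasts were sampled. None of the genes fixed beforehand passed between the routes, in a comparison that recovered 39% of simulated 2-fold changes. Il6, an inflammatory cytokine, was at 228 CPM ± 84.7 (SD, n = 5) in fibroblasts of the sort and 165 CPM ± 74.8 (SD, n = 8) in those of the mixtures. Acta2, which encodes alpha smooth muscle actin, was at 277 CPM ± 304 and 207 CPM ± 263, and Fap, which encodes fibroblast activation protein, at 32.95 CPM ± 13.46 and 21.98 CPM ± 10.97. The log2 fold changes, sort over mixture, were 0.43 (SE 0.31) for Il6, 0.42 (SE 0.91) for Acta2 and 0.58 (SE 0.34) for Fap. They were 0.40 (SE 0.41) for the chemokine Cxcl12, 0.30 (SE 0.62) for Tgfb1, 0.15 (SE 0.24) for Pdgfra and −0.16 (SE 0.32) for Pdpn, all with an adjusted p of 1 in edgeR's quasi-likelihood test. With the animal as a block, in the 5 animals with both libraries, none passed either. The values were then 0.34 (SE 0.20) for Acta2, 0.19 (SE 0.23) for Fap and 0.25 (SE 0.17) for Il6. Those of Cxcl12, Pdgfra, Pdpn and Tgfb1 were 0.45 (SE 0.17), 0.27 (SE 0.13), −0.04 (SE 0.14) and −0.11 (SE 0.15).

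No gene of 7640 tested passed the threshold in edgeR, 148 had an unadjusted p under 0.05, and DESeq2 called 12, all lower in the sort. With the animal as a block, in the 5 animals with both libraries, edgeR called 25 of 6920 genes, 4 higher and 21 lower in the sort. Without 377D the block called 8 genes, all lower, without 177B 41 (9 higher) and without 739 39 (5 higher). Of the 25 called with all 5 animals, 7 met the rule for naming, and these were mostly genes of leukocytes. The 25 also held Ctrb1 and Gkn3, which acinar and epithelial clusters make, and 2 haemoglobin genes. Cd52, a lymphocyte surface protein, fell by 4.14 on the log2 scale (SE 0.32, adjusted p = 5.36e-07), from 110 to 6.98 CPM on average. Igkc and Igha, parts of antibody chains, fell by 4.12 (SE 0.74) and 2.12 (SE 0.44). Wfdc17, a macrophage transcript, fell by 3.19 (SE 0.46), Arhgdib, a Rho regulator abundant in leukocytes, by 1.60 (SE 0.28) and the neutrophil attractant Cxcl2 by 1.30 (SE 0.23). Uba52, a ubiquitin-ribosomal fusion gene, rose by 0.91 (SE 0.16, adjusted p = 0.00994). Igkc, Igha and Uba52 share sequence with other genes, so their counts are uncertain.

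Of the 17 lists, 2 passed camera between the routes without the block. The antigen-presenting list was lower in the sort (6 members measured, none called over all genes or adjusted over the list alone, adjusted p = 0.00156), with log2 fold changes of −1.84 for Slpi, −1.29 for Cd74, the invariant chain of MHC class II, and −0.11 for Saa3. Its adjusted p was 0.314 with an estimated correlation. The list of dissociation stress genes was higher (13 measured, none called over all genes or adjusted over the list alone, adjusted p = 0.00156, and adjusted p = 0.642 with an estimated correlation), with 0.33 for Fos, 0.28 for Jun and 0.26 for Junb, all immediate early genes. The other 15 lists had adjusted p from 0.0513 (adventitial fibroblast) to 0.848 (proliferation). With the animal as a block the antigen-presenting list gave adjusted p = 7.7e-07 (2 members called lower, 4 adjusted over the list alone) and the dissociation list 1.65e-05, and 3 more lists passed: cytokines (higher, adjusted p = 0.00181), complement (higher, 0.0479, against a median below 0 without the block) and interferon response (lower, 0.0479). None of these 5 passed with an estimated correlation under the block (adjusted p 0.316 to 0.663).

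Markers of other cell types moved in the same comparison of fibroblast sums. Plasma cell markers were lower in the sort (4 measured, all 4 called lower adjusted over the list alone, camera adjusted p = 9.92e-12, and adjusted p = 0.0102 with an estimated correlation). Macrophage or monocyte markers were also lower (6 measured, 3 called lower adjusted over the list alone, adjusted p = 4.64e-09, and adjusted p = 0.0243 with an estimated correlation). Acinar markers were lower (adjusted p = 0.0022, and 0.248 with an estimated correlation), and erythroid markers, all haemoglobin genes, higher (3 measured, adjusted p = 4.19e-05, and 0.0728 with an estimated correlation). With the animal as a block both also passed with an estimated correlation: acinar markers at adjusted p = 0.0492 (2 measured, 1 called lower) and erythroid markers at 0.021 (3 measured, 2 called higher). The adjusted p was 0.0611 for perivascular, 0.13 for neutrophil, 0.21 for mesothelial and 0.436 for fibroblast markers, and the remaining marker lists had too few members measured. The count of calls without the block depended on single libraries: it was 18 without the sort of 468B, 8 without the mixture of 739, 6 without that of 177B, 2 without that of 591 and 1 without the sort of 739. Different clusters held most fibroblasts in different animals, cluster 8 (led by Crlf1, Cxcl14 and Tnc) in 739 and 177B by both routes and cluster 0 (led by Igf1, Cxcl12 and Sfrp4) in 377D, 0286 and 0892.

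Fibroblasts with Acta2 were then compared with fibroblasts with Fap, since the study concerned functional differences among cancer-associated fibroblasts. Both genes were detected in few cells. After thinning to 1000 UMIs per cell, 7.74% ± 6.65 (SD, n = 5) of fibroblasts were Acta2-positive in the triple-negative sorts and 5.96% ± 7.63 (SD, n = 8) in the mixtures. Fap-positive cells made up 3.13% ± 1.20 and 2.03% ± 0.82. Without thinning the shares were 18% ± 14.8 and 14.5% ± 15.4 for Acta2, and 13.5% ± 8.07 and 12.4% ± 11.2 for Fap. As background in the mixtures alone, thinned B cell-like cells had Acta2 in 0.045% and T cell-like cells in 0.086%. Fap was found in 0 of 4635 B cell-like cells of the mixtures, which allows a share of up to 0.065%. In the sorts, thinned B cell-like cells could be counted in 1 library, with Acta2 in 0.0%. Unthinned, they had Acta2 in 3.23% (2 libraries, 0.0% and 6.45%), against 0.142% in the mixtures, so a low background is not shown for the sorts. The median depth was 1440 to 2964 UMIs in the B cell-like cells of the mixtures and 1862 to 13814 in the fibroblasts of both groups. Thinning left out 168 fibroblasts of the sorts and 46 of the mixtures.

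The routes differed by 1.78 points for Acta2 (exact permutation test, p = 0.6845, n = 5 and 8) and by 1.10 points for Fap (exact permutation test, p = 0.0746), neither of them separable from the spread between libraries. A single random draw of the thinning gave 1.65 points for Fap (exact permutation, p = 0.049), and 27 of 100 further draws gave p under 0.05 for Fap and 0 for Acta2. Within animals the mean Acta2 difference was −0.22 points (exact sign-flip test, p = 1.0, and exact permutation unpaired, p = 0.9603), although the sort was higher in 4 of 5 animals, and the Fap difference was 0.86 points (exact sign-flip, p = 0.4375, higher in the sort in 3 of 5 animals). Without the sort of 177B the Acta2 difference was −0.98 points. The Fap difference passed without the sort of 377D (p = 0.0222), the sort of 739 (p = 0.0444) or the mixture of 177B (p = 0.0114, all exact permutation tests).

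**Figure D3:**
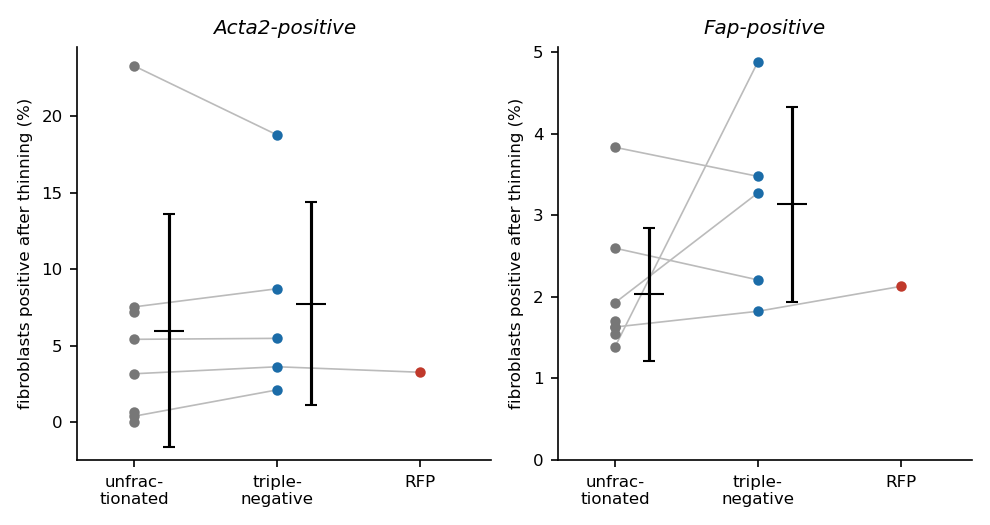
Share of fibroblast-like cells (%) expected to be positive for Acta2 (left) or Fap (right) after thinning to 1000 UMIs per cell, per library and route. Points are libraries, grey lines join libraries of 1 animal and black bars give mean ± SD; the Acta2 share ranges up to 23.3% in the mixture of animal 177B and the Fap share up to 4.88% in the sort of animal 314B.

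Animals 177B, 377D and 739 had enough cells of each kind, with 471 Acta2-positive and 302 Fap-positive fibroblasts. Acta2 lies on chromosome 19 (34241090 to 34255590) and Fap on chromosome 2 (62500943 to 62574075, GRCm38). Acta2-positive cells had far higher levels of other contractile genes. Tagln, which encodes the actin-binding protein transgelin, averaged 1042 CPM ± 895 (SD, n = 3 animals) against 86.8 CPM ± 101.95 in Fap-positive cells, a log2 fold change of 3.88 (SE 0.22, edgeR adjusted p = 7.8e-05). The tropomyosin gene Tpm2 rose by 2.45 (SE 0.16, adjusted p = 1.48e-04) and the myosin light chain gene Myl9 by 2.74 (SE 0.24, 0.00102). The smooth muscle actin gene Actg2 was also called (adjusted p = 0.00112), with 285 UMIs in Acta2-positive and 1 UMI in Fap-positive cells, a pooled CPM ratio of 134 whose 95% counting interval runs from 23.8 to 5300. Fap-positive cells had higher levels of Cxcl13, a B cell attractant, by 3.31 on the log2 scale (SE 0.28, adjusted p = 8.75e-04), and of Ace, angiotensin-converting enzyme, by 1.76 (SE 0.16, adjusted p = 0.00112). Cxcl13 averaged 1404 CPM ± 2345 (SD, n = 3 animals) in Fap-positive and 110 CPM ± 177 in Acta2-positive cells. Its level differed between animals: over all fibroblast-like cells it was 1195 CPM in 177B, 52.65 in 377D and 140.32 in 739.

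The test called 143 of 8390 genes, 76 higher in Acta2-positive and 67 higher in Fap-positive cells, and 124 met the rule for naming. The other named genes higher in Acta2-positive cells were Igfbp2 (3.66, SE 0.55), an IGF-binding protein, Defa30 (2.96, SE 0.39), Tinagl1 (2.84, SE 0.38), Cenpa (2.81, SE 0.48), a centromere histone, H19 (2.51, SE 0.52), an imprinted non-coding RNA, Cdh2 (2.05, SE 0.34), N-cadherin, Trem2 (1.89, SE 0.25), a receptor best known from macrophages, and Cryab (1.86, SE 0.37), a small heat shock protein. Their adjusted p lay between 0.00747 and 0.0464. Defa30 belongs to a family of near-identical genes, so its count is uncertain. The other named genes lower in Acta2-positive cells were Apod (−3.93, SE 0.82), apolipoprotein D, Prg4 (−3.00, SE 0.53), lubricin, Lrg1 (−2.91, SE 0.59), Gc (−2.30, SE 0.28), vitamin D-binding protein, Ntrk2 (−1.99, SE 0.39), a neurotrophin receptor, and Ifi207 (−1.97, SE 0.32), an interferon-induced gene with close relatives. Below these stood Scara5 (−1.90, SE 0.27), Ggt5 (−1.83, SE 0.37), Abca8a (−1.54, SE 0.27) and Adh1 (−1.52, SE 0.32), an alcohol dehydrogenase. Their adjusted p lay between 0.00702 and 0.0475.

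Genes fixed beforehand did not pass. Il6 averaged 163 CPM ± 50.2 in Acta2-positive and 208 CPM ± 60.4 in Fap-positive cells (SD, n = 3), with a log2 fold change of −0.37 (SE 0.15, edgeR adjusted p = 0.298). The values were −1.38 (SE 0.45, adjusted p = 0.179) for Cxcl12, −0.61 (SE 0.20, 0.176) for Pdgfra, 0.26 (SE 0.15, 0.497) for Pdpn and −0.22 (SE 0.29, 0.80) for Tgfb1.

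**Figure D4:**
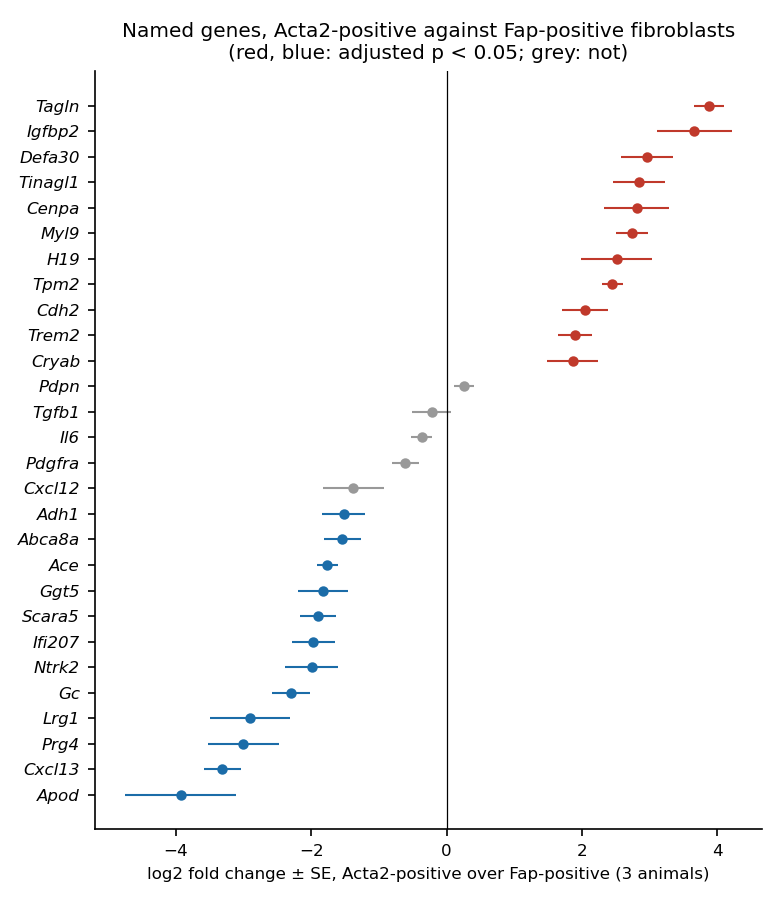
Log2 fold change ± SE of named genes, Acta2-positive over Fap-positive fibroblasts, in edgeR's test with the animal as a block (3 animals), leaving out Actg2, which had 1 UMI in Fap-positive cells. Tagln (3.88) lies at the top, Apod (−3.93) and Cxcl13 (−3.31) at the bottom, and 5 genes fixed beforehand (grey) did not pass.

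Among the lists, the contractile apparatus stood highest: 7 of 8 measured members were called higher over all genes and all 8 adjusted over the list alone (camera adjusted p = 1.34e-52, and adjusted p = 0.102 with an estimated correlation). The myofibroblastic list, which shares Tagln, Tpm2, Myl9 and Tpm1 (1.33, SE 0.17) with it, had 5 of 10 members higher and 1 lower by either count (adjusted p = 4.16e-17, and 0.102 with an estimated correlation). Proliferation genes were higher (2 of 4 called, 3 adjusted over the list alone, adjusted p = 5.12e-08, and 0.159 with an estimated correlation), among them Stmn1, a microtubule regulator, at 1.81 (SE 0.28) and Birc5, survivin. Birc5 had 173 UMIs in Acta2-positive and 4 in Fap-positive cells, a pooled ratio of 20.3 (7.78 to 75.3).

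Complement genes were lower in Acta2-positive cells (3 of 7 called, 6 adjusted over the list alone, adjusted p = 7.27e-07, and 0.273 with an estimated correlation), with −0.94 (SE 0.18) for C1ra, −0.89 (SE 0.17) for C4b and −0.80 (SE 0.17) for Cfh. Also lower were the dissociation stress list (none of 13 called, 9 adjusted over the list alone, adjusted p = 7.99e-06, and 0.273 with an estimated correlation), the adventitial list (none of 7, 3, adjusted p = 5.67e-04, and 0.378) and the basement membrane list (1 of 9, 2, adjusted p = 6.97e-04, and 0.366), in which Lama4, a laminin chain, fell by 0.86 (SE 0.17). The inflammatory list was lower too (none of 12, 5, adjusted p = 0.00189, and 0.33), as was the chemokine list (1 of 10, 3, adjusted p = 0.00572, and 0.378), whose called member was Cxcl13. Uncalled members had −0.80 (C3), −0.79 (Clec3b), −0.22 (Cxcl1), −0.88 (Ly6a), −0.76 (Dpt), −0.56 (Jun), −0.50 (Fos) and −0.50 (Junb). In cells of cluster 8 alone, C3 (0.20), Clec3b (0.93) and Cxcl1 (0.18) went the other way without being called, and no other of these did. The antigen-presenting list was higher (none of 5, 3, adjusted p = 8.97e-04, and 0.273), with 1.30 for Slpi, 0.91 for Cd74 and 0.50 for Saa3. Cd74 was −0.65 in the sorts alone and Saa3 −0.39 at 2 UMIs, neither called, while Slpi did not reverse. The hypoxia and glycolysis list was higher as well (none of 9, 4, adjusted p = 0.00439, and 0.432), with 0.99 for Eno1, 0.63 for Ldha and 0.39 for Aldoa. In these sentences the first count is over all genes, the second is adjusted over the list alone, and the last p is with an estimated correlation.

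The other 6 lists did not pass. Matrix remodelling genes went both ways (2 of 12 higher, 1 lower, with 5 and 3 adjusted over the list alone, adjusted p = 0.0955): the metalloprotease inhibitors Timp1 (1.61, SE 0.22) and Timp3 (1.30, SE 0.18) were higher and the metalloprotease Mmp11 (−1.26, SE 0.26) lower. In the TGF-beta list (13 measured, adjusted p = 0.228) the target gene Serpine1 rose by 1.14 (SE 0.16) and the receptor gene Tgfbr2 fell by 0.70 (SE 0.14), and 2 and 1 passed adjusted over the list alone. In the cytokine list (7 measured, adjusted p = 0.165) Il11 was called, at 1.67 (SE 0.31), and in the growth factor list (8 measured, adjusted p = 0.462) Fgf7, at −1.29 (SE 0.24), each also the 1 member past the threshold adjusted over the list alone. No fibrillar collagen (6 measured, adjusted p = 0.228) or interferon response gene (8 measured, adjusted p = 0.801) was called by either count.

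Epithelial markers were also higher in Acta2-positive cells (4 measured, none called over all genes, 3 adjusted over the list alone, adjusted p = 0.00184, and adjusted p = 0.434 with an estimated correlation). Perivascular markers did not move together: 1 of 3 measured was called higher and their median log2 fold change was −0.07 (range −0.23 to 1.71), although camera gave an adjusted p of 0.036 (0.434 with an estimated correlation). The adjusted p was 0.0908 for mesothelial, 0.106 for fibroblast, 0.186 for macrophage and 0.784 for erythroid markers. Acta2-positive cells were deeper, with median UMIs of 11633, 5574.5 and 16620.5 in 177B, 377D and 739 against 8814, 4221 and 12922 in Fap-positive cells. They also fell in different clusters: cluster 8 held 21.8% of Acta2-positive and 3.0% of Fap-positive cells in 377D, 75.9% and 51.8% in 177B, and 95.8% and 98.7% in 739. Cluster 36, led by Cxcl13, Serpina3n, Cxcl12 and Apod, held 4.5% and 33.9% in 177B, and cluster 12 held 3.2% and 19.5% in 377D.

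DESeq2 called 69 genes, 65 of them among the 143. Leaving out 177B left 12 genes, leaving out 377D gave 420 and leaving out 739 gave 255, so the count rests on which of the 3 animals enter.

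The RFP sort was the alternative route to aSMA-expressing fibroblasts, and its 1 library was set beside the other 2 libraries of the same animal, 377D, with no replicate and no test. In fibroblast-like cells Acta2, the gene of the reporter's name, was not higher in the library labelled as RFP-sorted than in the triple-negative sort. Fibroblasts of the RFP library had 92.1 CPM of Acta2 (95% Poisson interval 84.7 to 100.1), against 106 CPM (99.8 to 112) in the triple-negative sort and 83.5 CPM (69.2 to 99.8) in the mixture. The ratio of RFP to triple-negative was 0.87 (0.78 to 0.96) and that of RFP to mixture 1.10 (0.90 to 1.36). Acta2-positive fibroblasts after thinning made up 3.25%, 3.61% and 3.15% of the RFP, triple-negative and unfractionated libraries. Fibroblast-like cells made up 85.8% (exact interval 84.4 to 87.1) of the RFP library, 85.5% (84.2 to 86.8) of the triple-negative sort and 10.1% (9.14 to 11.2) of the mixture. Perivascular-like cells, left out of these Acta2 values, lay in clusters 31 and 29. These held 2.82% and 1.04% of the RFP library, 2.63% and 0.78% of the triple-negative sort and 0.26% and 0.09% of the mixture.

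Across 10614 genes with at least 50 UMIs the RFP and triple-negative fibroblasts correlated at r = 0.9916 (log2 CPM, across genes, which are not independent replicates). In 915 genes the Poisson intervals did not overlap, 553 higher and 362 lower in the RFP library. The ratios named by the rule were led by Trem2 (3.98), Cenpf (3.82), a centromere protein gene, Calca (3.69), Fcer1g (3.13) and Spp1 (2.92), osteopontin, which stood at 371 CPM (356 to 387) against 127 CPM (121 to 134). Also higher were Actg2 (2.79), Defa30 (2.73), Pmaip1 (2.56), Cxcl9 (2.53), Etaa1os (2.53), the cell cycle kinase gene Cdk1 (2.44) and Gstp1 (2.39). Ccl21a, a lymphatic chemokine, was 7.63-fold lower in the RFP library, Igfbp2 6.62-fold, Gkn3 3.32-fold, Igha 2.84-fold, Ap1g2 2.5-fold and Saa3 2.48-fold. Smaller ratios were those of Zfp212 (2.43-fold lower), Foxred1 (2.40), Nppc (2.31), Prep (2.20), Pthlh (2.15) and Igkc (2.09). Ccl21a, Defa30, Gstp1, Igha and Igkc have near-identical relatives, so their counts are uncertain. Il6 stood at 146 CPM (136 to 156) in the RFP library, 119 (113 to 126) in the triple-negative sort and 92.5 (77.5 to 110) in the mixture, and Fap at 20.98 (17.51 to 24.95), 18.4 (15.9 to 21.1) and 15.3 (9.59 to 23.2). The RFP to triple-negative ratio was 0.90 for Cxcl12, 1.13 for Pdgfra, 1.04 for Pdpn and 1.0 for Tgfb1.

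**Figure D5:**
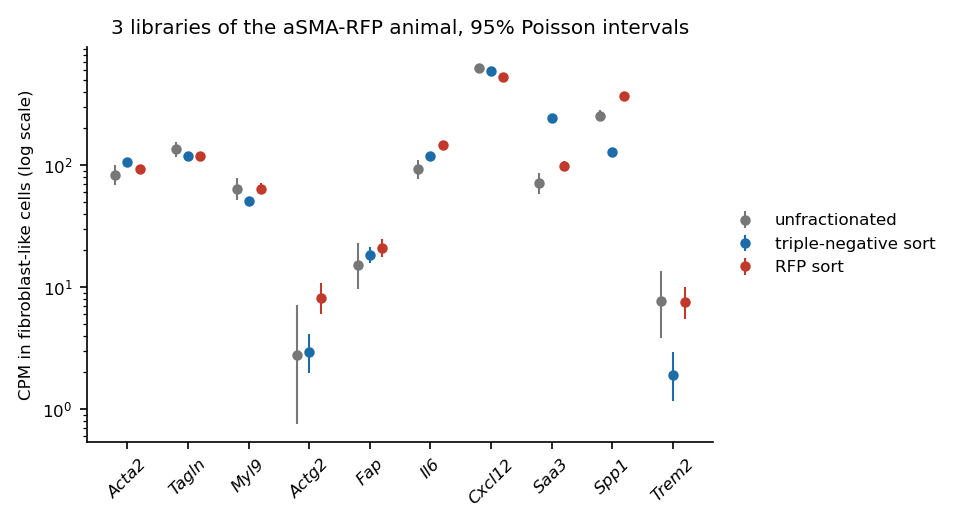
CPM (log axis) of 10 genes in fibroblast-like cells of the 3 libraries of the aSMA-RFP animal, with exact 95% Poisson intervals. Acta2 lies between 83.5 and 106 CPM in all 3 libraries, and Spp1 is higher in the RFP library (371 CPM) than in the triple-negative sort (127 CPM).

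Against 10000 random lists, the contractile list lay at the 72.5th percentile of the RFP to triple-negative ratio (median log2 ratio 0.07) and the myofibroblastic list at the 63.8th (0.04). By intervals that do not overlap, 4 of 12 myofibroblastic members were higher and 0 lower, and 2 of 9 contractile members higher and 1 lower. Over all 10614 genes 553 were higher and 362 lower, but intervals are narrower for abundant genes, so these shares are not directly comparable. Tagln had a ratio of 1.01 and Myl9 1.26. The proliferation list lay at the 100th percentile (0.71), the dissociation stress list at the 98.9th (0.14), the antigen-presenting list at the 98.0th (0.21) and the chemokine list at the 96.6th (0.13), while the interferon list lay at the 2.7th (−0.15). By intervals, antigen-presenting members (2 of 6 higher, 1 lower) and chemokines (4 of 12 higher, 3 lower) went both ways. Higher were 8 of 13 dissociation and 2 of 5 proliferation members with 0 lower, and 3 of 8 interferon members were lower with 0 higher. The remaining 10 lists lay between the 8.4th (complement) and the 91.6th (inflammatory) percentile. Acinar markers (10 measured) lay at the 100th (0.34), macrophage markers (2 measured) at the 99.9th (0.60) and plasma cell markers (3 measured) at the 0th percentile (−1.07), and the 6 other marker lists measured between the 11.6th and the 86.4th.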

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

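The search for samples far from the rest of their group was set before the data were examined, and no test was added to it afterwards. It covered 44 sets of shares in groups of 4 to 10 libraries and marked 13. The rule was taken to mark about 1 group in 20 by chance. Its rate for skewed shares such as these is not given here, so 13 is not shown to be an excess. The classes of a library sum to a whole, so the sets are not independent either. No explanation was tested for the values below.

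Among the 8 unfractionated mixtures, animal 177B stood apart in 4 measures. Macrophage- or monocyte-like cells made up 55.4% there against 25.4% in the nearest library (median 17%), neutrophil-like cells 18.1% against 6.14% (median 1.94%) and mesothelial-like cells 1.96% against 0.399% (median 0.177%). Acta2-positive cells made up 23.3% of its thinned fibroblasts against 7.53% (median 4.28%). The epithelial or cancer class held 84.0% of animal 739 against 14.9% in the nearest mixture (median 3.77%). In the nearest, 177B, the class was cluster 11 alone. That cluster had 2 endocrine markers and 1 epithelial one among its top genes, though all 11 epithelial markers met the naming rule. In 739 most cells of the class lay in cluster 6 (1391 cells, 94.2% of the cluster), led by Cst6, the imprinted RNA H19 and Hmga2, and in cluster 19 (531 cells, 91.9%), led by Hmga2, Prkg2 and Neto2. Both clusters met the naming rule with 4 of the 11 epithelial markers and had 0 among their top genes. Acinar-like cells, the enzyme-secreting cells of the pancreas, made up 5.86% of animal 591 against 1.86% (median 0.444%).

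Among the 5 triple-negative sorts, animal 468B stood apart in 6 classes. Leukocytes remained in it although CD45-positive cells were gated out: macrophage- or monocyte-like cells 12.0% against 1.34% in the nearest library (median 1.14%), B cell-like cells 6.64% against 1.25% (median 0.268%), dendritic-like cells 5.35% against 1.08% (median 0.617%) and T cell-like cells 4.71% against 1.34% (median 1.05%). NK-like cells made up 2.14% and were not found in the other sorts, where the exact binomial interval around 0 reaches up to 0.984% in the smallest library. Perivascular-like cells made up 44.5% of that sort against 8.23% (median 4.83%). In the sort of animal 177B, mesothelial-like cells made up 26.7% against 2.77% (median 2.67%).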

How the results depend on the processing

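The highest doublet scores, the 5 animals with both libraries unpaired, the block for lists, the single thinning draw, minimums of 5 cells and cluster 8 alone were chosen after the data were seen; the other settings were planned. The shares of classes in the mixtures moved by less than 1 SD in all 65 values recomputed. That SD is the spread between mixtures, and for neutrophil-, acinar- and mesothelial-like cells it exceeded the mean. The bound is therefore loose and could hardly be passed by such classes. Of the named genes, 848 of the planned values kept direction and side of the threshold, 86 lost and 41 gained a call and 17 reversed. Of the added ones 203, 31, 17 and 8 did so. These totals include genes that had no call to lose. For Acta2-positive against Fap-positive cells, 28 of 56 named genes lost their call without 177B, 37 of 57 with no block and 12 of 56 with DESeq2. Without 377D 1 of 56 did, and without 739 5 of 55. The cause was not tested for any change below unless fewer animals or cells gave it.

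With the animal as a block, the fibroblast share difference was 52.83 points with p at the smallest value 5 pairs can give (exact sign-flip), the Acta2-positive difference −0.22, the route comparison 25 genes, and the lists of cytokines 0.00181, complement 0.0479 and interferon 0.0479; it also brought acinar (0.0492) and erythroid markers (0.021) past the threshold with an estimated correlation, and changed no other call outside single genes. Unpaired in those animals the Acta2-positive difference was −0.22. Leaving out 1 library gave 45.31 to 63.00 points for fibroblasts, −0.98 to 4.26 for Acta2 and 0.66 to 1.43 for Fap; 1 thinning draw gave 1.65 for Fap.

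Between routes the count of genes was 12 with DESeq2, 44 with no filter, 17 without Scrublet doublets, 8 without the highest scores and 0 to 18 leaving out 1 library. For Acta2-positive against Fap-positive cells it was 69 with DESeq2, 611 with no filter, 1 with no block, 236 at a minimum of 5 cells, at that minimum 16 of 475 genes tested in thinned cells and 6 at 2 UMIs, 377 in cluster 8 (177B and 739 alone) and 12 to 420 leaving out 1 animal. At the minimum of 20 cells, 2 UMIs and unfractionated cells alone left 0 animals and thinning 1, so these were not run.

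With an estimated correlation the adjusted p between routes was 0.314 for the antigen-presenting and 0.642 for the dissociation list. For Acta2-positive against Fap-positive cells it was 0.102 for the contractile and myofibroblastic lists, 0.159 for proliferation, 0.273 for complement, dissociation and antigen-presenting, 0.33 for inflammatory, 0.366 for basement membrane, 0.378 for adventitial and chemokines and 0.432 for hypoxia. The stricter filter on cells moved the fibroblast share of animal 377D to 87.2% (RFP) and 86.8% (triple-negative).

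Named genes that reversed had adjusted p of at least 0.195. Between routes, Tgfb1 was −0.11 with the block, −0.08 unpaired in the same animals and −0.27 to 0.66 leaving out 1 library; Saa3 was 0.30 with the block, 0.69 without the highest scores and −1.10 to 1.32; Pdpn 0.00 unpaired and −0.41 to 0.01; Acta2 −0.46 to 1.13; Pdgfra −0.11 to 0.24; Uba52 −0.30 to 0.54; Junb −0.04 to 0.38. For Acta2-positive against Fap-positive cells, Cd74 was −0.65 in the sorts alone, Tgfb1 0.27 at 5 cells and −0.52 to 0.39 leaving out 1 animal, Saa3 −0.39 at 2 UMIs and −0.01 to 1.16, Cxcl1 0.18 in cluster 8 and −0.39 to 0.00, Clec3b 0.93 and C3 0.20 in cluster 8. Depth limits the positive shares, since 1 UMI per cell decides them.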

Other observations

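The tests of free RNA and doublets had predictions written before their results were seen, and all other tests in this part were chosen after. Il6 was not a fibroblast transcript alone. It averaged 235 CPM ± 232 (SD, n = 3 animals) in mesothelial-like cells, 175 CPM ± 60.8 (n = 8) in fibroblast-like, 128 CPM ± 110 (n = 5) in perivascular-like and 100.94 CPM ± 151 (n = 8) in macrophage- or monocyte-like cells, where 177B stood at 468.78 and the other animals between 28.76 and 100.32. The mesothelial value was 468 CPM in 177B, 232 in 739 and 4.15 in 377D. Cxcl12 averaged 469 CPM ± 193 (n = 8) in fibroblast-like cells, against 163 in endothelial-like cells and 107 (n = 3) in mesothelial-like cells, but in 739 mesothelial-like cells (166.59) stood above fibroblast-like cells (128.7). Tgfb1 averaged 240 CPM ± 34.1 in macrophage- or monocyte-like cells, 232 CPM ± 53.8 in B cell-like cells and 90.4 CPM ± 82.9 in fibroblast-like cells. In 739 fibroblast-like cells (258) stood above macrophage- or monocyte-like cells (240), and in 177B perivascular-like cells did (225 against 202). Il11 averaged 8.72 CPM ± 13.8 in fibroblast-like cells and was highest in 739, at 41.5 CPM. These class levels were not tested against each other.

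Mesothelial-like cells carried several genes of the antigen-presenting list. Saa3, an acute phase protein gene, averaged 8790 CPM ± 7995 (SD, n = 3) in them and 408 CPM ± 619 (n = 8) in fibroblast-like cells. By animal it stood at 15805 in mesothelial-like and 1683 in fibroblast-like cells of 177B and at 10478 and 1048 in 739, but at 85.1 and 224 in 377D, the opposite direction. Cd74 averaged 2778 CPM ± 2746 and 229 CPM ± 225, with 473, 2046 and 5816 in mesothelial-like cells of 177B, 739 and 377D. Slpi, a protease inhibitor gene, averaged 7616 CPM ± 5090 and H2-Ab1, an MHC class II chain, 667 CPM ± 522 in mesothelial-like cells (219 to 1241). Acta2 was far higher in perivascular-like cells (4630 CPM ± 1363, n = 5) than in fibroblast-like cells (220 CPM ± 244), while Fap stood at 36.3 CPM ± 24.6 and 25.2 CPM ± 11.5. Acta2 and Fap were found together in fibroblasts of 3 of the 5 triple-negative sorts: of Fap-positive cells, 54.5% (61 of 112) in 177B, 36.8% (39 of 106) in 739 and 12.6% (22 of 175) in 377D also had Acta2, and 0 of 35 in 314B and 0 of 4 in 468B. After thinning, both were found in 0.709%, 0.269% and 0.070% of fibroblasts of 177B, 739 and 377D, against 0.654%, 0.193% and 0.066% if the genes were independent, ratios of 1.08, 1.40 and 1.07. In 314B and 468B both were found in no cell, against 0.102% and 0.179% if independent. The mixtures, with 48 to 323 fibroblasts each, went both ways: 3.64 in 377D, 2.44 in 0892, 1.16 in 739, 0.85 in 177B, 0.74 in 0286, 0.19 in 468B and 0.00 in 314B (none could be formed in 591), and the library labelled as RFP-sorted had 0.78.

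Immune transcripts were lower in fibroblasts of the triple-negative sort, which removes leukocytes. Free RNA from immune cells remains a candidate explanation: UMIs per cell of the 21 genes called lower with the block were 0.81 times those in other non-immune cells of the same mixture (median over genes, then over animals), with 5.54 in 739 as the exception. Summed over genes the ratio was 0.12, 0.26, 0.06 and 0.16 in 177B, 314B, 377D and 468B and 1.38 in 739, but Ctrb1 and Gkn3, which acinar and epithelial clusters make themselves, supplied 53.4% to 94.6% of the sum in those 4 animals, and without them it was 0.92, 1.25, 0.95, 0.35 and 1.74, so 468B is an exception too. Doublets remain open as well, because the 5% of fibroblasts richest in these UMIs held 6.26 times the share an equal rate gives (1.76 to 10.69 over animals), though that null ignores depth and fibroblasts with antigen-presenting genes of their own would give the same. Without the highest Scrublet scores the summed CPM of these genes in mixture fibroblasts went from 1736.1 to 882.6 in 377D. It hardly fell or rose in 177B (1227.8 and 1227.8), 314B (13437.6 and 14373.4), 468B (3891.5 and 3828.1) and 739 (1346.2 and 1392.3). That cannot decide, since scores of a caller that marked so few cells may miss doublets. Splits decide nothing here: without the block the real split gave 0 genes, so all 100 of 100 splits of the 13 libraries gave as many (highest other 10), and with the block the real split gave 25 genes and the highest of the 15 others 20, too few splits for a share under 0.05.

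Contractile genes were higher in Acta2-positive than in Fap-positive fibroblasts. The observed excess of 9 perivascular markers was at most 0.01 of what perivascular RNA would need in any of the 3 animals (0.061 with the profile of cluster 31, and at most 0.04 with Des, the marker left out, included), which argues against that source. Depth is argued against as the whole cause: in cells thinned first, with at least 5 cells per sum and 4 animals, 3 of the 4 genes could be tested and had a median log2 fold change of 2.39 (Tagln 4.62, Tpm2 2.39 and Tpm1 1.43, the last no longer called in edgeR, adjusted p = 0.0569), against 3.88, 2.45 and 1.33 unthinned in 3 animals. Of 4 splits of the 3 animals the real one gave 143 genes and the highest other 0, too few splits for a share under 0.05. No biological explanation was tested.

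Acta2 was not higher in fibroblast-like cells of the library labelled as RFP-sorted than in those of the triple-negative sort of that animal. Lower depth is argued against, since thinned Acta2-positive shares had a ratio of 0.90 and the CPM ratio was 0.87 (0.78 to 0.96). A swap of both labels stays open: the library labelled triple-negative exceeded the mixture by a ratio of 1.27 (1.05 to 1.54), the direction a swap with weak enrichment would give, and a bound of 2-fold first set for this test was dropped after the value was seen, since how far the RFP gate enriches Acta2 was not measured. A weak enrichment by the RFP gate stays open too: genes higher in Acta2-positive fibroblasts of the other animals had a median log2 ratio of 0.03 (199 genes, 80.3rd percentile, random lists −0.019 to 0.048), and genes lower in them −0.03 (186 genes, 0.4th percentile, outside −0.017 to 0.048), the direction an enrichment would give. The bound written for the first list alone would have excluded it, but was judged wrong after the value was seen, since a median inside the random range does not exclude a small shift.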
